A study of Homo sapiens with 4 samples.

How the data were processed

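RNA was sequenced from 4 human acute myeloid leukemia cell lines, HL60, KG1a, THP-1 and MonoMac-1, with 1 library per line. The title of the THP-1 sample carries a suffix, "tr", that no label explains, so whether that culture was treated or modified is not known; its group was taken from the cell line that the labels give. Per the labels' protocols, RNA was extracted with TRIzol and made into standard Illumina libraries. The submitters' processing notes name CASAVA 1.8.2 and the hg19 build. The aligner, the gene annotation, strand handling and any read filter are not given in the sources used here.

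The authors deposited 1 table per line, without a header, in which each of 21893 entries gave a gene symbol, its chromosome, start and end, and 2 values. The first value is the RPKM that the authors deposited, a gene's abundance per kilobase of its length, scaled to the library total. The second is a whole-number coverage signal that the authors deposited without a stated unit. From its values it was read as the sum of sequenced bases lying on the gene, because the commonest low value was 200 and, in 3 libraries, 44.8% to 49.7% of low values were multiples of 100. In MonoMac-1 that share was 12.7%, with values just under the multiples, so the reads of this library look trimmed or clipped where those of the other 3 do not. In every library the RPKM equalled this sum divided by a gene length and by 1 library total. The sums came to 8.72 gigabases for HL60, 10.2 for KG1a, 6.04 for THP-1 and 13.6 for MonoMac-1. The commonest low values match reads of 100 bases, a read length inferred from the values. Count models were not used, since neither value is a count of reads.

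Values were analysed as log2(RPKM + 1). This pseudocount of 1 understates the change of weakly expressed genes. For the 28 symbols listed more than once the entry with the highest mean was used, which left 21865 symbols, and 12976 of them reached an RPKM of 1 in at least 1 line and are called measured. In all libraries 23 symbols placed on both X and Y were listed at 0, among them IL3RA and CD99, so these genes were not assessed. Coordinates are those of the deposited tables (hg19, starts as listed); a reference genome of another build was not used. Reads of overlapping or antisense genes and of near-identical copies (HLA-DRB1 and HLA-DRB5, metallothioneins, histones, globins, tryptases) may be split or shared by the authors' counting, and their values are uncertain.

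That THP-1 and MonoMac-1 carry the MLL-AF9 (KMT2A-MLLT3) fusion and that HL60 and KG1a do not is general knowledge of these lines and is not stated in the labels. THP-1 and MonoMac-1 were compared with HL60 and KG1a by counting genes whose lower value in one pair of lines was at least 4 times the higher value in the other pair. The same count was made for the other 2 splits of the lines. The difference between the lowest value of one pair and the highest of the other is called the gap. limma 3.58.1 (R 4.3.3; lmFit and eBayes with trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05) was fitted with the line as the unit, which left 2 residual degrees of freedom. The p-values therefore measure the spread between different lines and not between cultures of a line. The gene lists were tested with camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. Both were adjusted over the 19 lists with at least 5 measured members. With the preset correlation camera sets a list against the other genes, and its p-value does not measure the spread between lines. With the estimated one it also uses the 2 residual degrees of freedom, so a lost call may come from those as well as from the correlation. THP-1 against MonoMac-1 and HL60 against KG1a were compared without a test, as differences of 1 library each. The median of each list was placed by its percentile among 10000 random lists of the same size drawn from 20 bins of mean expression. Genes of a random list were drawn independently, whereas list members may vary together (estimated correlation up to 0.685, for the histone list). An extreme percentile is therefore weaker evidence than it looks and is not a p-value. Line-restricted genes were those at least 8 times above the highest of the other 3 lines. Pearson and Spearman correlations were taken across the measured genes, which are not independent replicates.

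Before the data were examined, the tests, most of the alternatives, 22 gene lists and the rule for naming genes were fixed. The lists were RET with its co-receptors and ligands, receptor tyrosine kinases, HOXA and HOXB clusters, MLL-fusion target genes outside HOXA, MLL and its fusion-partner complex, monocyte, granulocyte, stem and progenitor, T and NK cell, B cell, erythroid and megakaryocyte, and stromal and epithelial markers, HLA class II, inflammatory and chemokine, interferon-stimulated and proliferation genes, surface antigens studied as drug targets, the BCL2 family, copy-number landmarks of HL-60, reference genes and core histone genes. Of 468 list members 467 were found in the tables, 6 of them under an older symbol. The values of 1 list member are not reported here. The named genes were the 12 with the largest gap in each direction between the pairs of lines, the 10 with the largest difference in each direction within each pair, the 6 with the largest gap above the other lines for each line, and any list member; small RNA genes, unnamed loci and genes of the Y chromosome were left out.

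Counting error of RET was given as an exact Poisson interval at 95% on fragments of 200 bases, with a floor of 3 fragments; such intervals cover counting error only. The limma fit and the gap rule were tested on simulated data for THP-1 and MonoMac-1 against HL60 and KG1a with 12976 genes. At a spread between lines of 0.51 on the log2 scale, limma called 64 of 100 genes simulated as 4-fold changed and 100 of 100 simulated as 16-fold changed, with 4 false calls, and the 4-fold gap rule took 18 and 100 of them. Every simulated gene had the same spread. The measured genes did not, with limma standard errors such as 0.37 for FCGRT and 3.47 for MPO. The simulated shares therefore do not give the power of limma in these data. The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at RPKM 5, median-of-ratios scaling, quantile normalization, averaging of repeated entries, leaving out each line, limma without trend, the estimated correlation, and 2-fold and 4-fold rules. The removal of a KG1a share from HL60 was added after the data were seen. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for all other steps.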

Results

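Steady-state RNA was measured by sequencing in 4 cultured lines of human acute myeloid leukemia. HL60 is a myeloblastic to promyelocytic line, KG1a is an immature line that expresses CD34, and THP-1 and MonoMac-1 are monocytic lines that carry the MLL-AF9 fusion. Each line was represented by 1 library, so no value had a replicate check. The title of the THP-1 sample carries an unexplained suffix ("tr"), and whether that culture was treated or modified is not known. The libraries held 6.04 (THP-1) to 13.6 (MonoMac-1) gigabases on genes. These made up 83.8% to 88.5% of the total behind the RPKM, a total inferred from genes whose length behind the RPKM matched their genomic span. Between 10569 genes in HL60 and 11346 in THP-1 reached 1 RPKM. The most abundant transcripts were PRG2 in HL60 at 7020 RPKM, TPT1 in KG1a at 3012, RPS18 in THP-1 at 4902 and SRGN in MonoMac-1 at 13925. Median-of-ratios scaling would have moved the libraries by -0.04 (MonoMac-1) to 0.05 (THP-1) on the log2 scale.

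The series title names the receptor tyrosine kinase RET, and RET was most abundant in the MLL-AF9 lines. RET (chromosome 10, 43572517 to 43625797, hg19), the receptor for ligands of the GDNF family, reached 47.8 RPKM in THP-1 (95% counting interval 46.9 to 48.7) and 14.6 in MonoMac-1 (14.3 to 14.97). It stood at 2.74 RPKM in HL60 (2.56 to 2.93) and at 0.0175 in KG1a (0.00696 to 0.0364), where the value rested on 6.8 fragment equivalents. The level in THP-1 was thus 17.4 times that in HL60 and 3.27 times that in MonoMac-1, and MonoMac-1 exceeded HL60 by 5.33 times. RET ranked as the highest of 54 receptor tyrosine kinases in THP-1 (rank 1), and held rank 3 in MonoMac-1, 9 in HL60 and 31 in KG1a. The co-receptors through which RET binds its ligands were scarce: of the 10 genes of the RET list only RET and GFRA1 were measured, and GFRA1 reached 1.57 RPKM in KG1a but was listed at 0 in THP-1 and MonoMac-1. GFRA2, GFRA3, NRTN, ARTN and PSPN stayed under 1 RPKM in all 4 libraries. The list held 1 gene (RET) at least 4-fold higher in both MLL-AF9 lines and was too small to be tested.

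**Figure D1:**
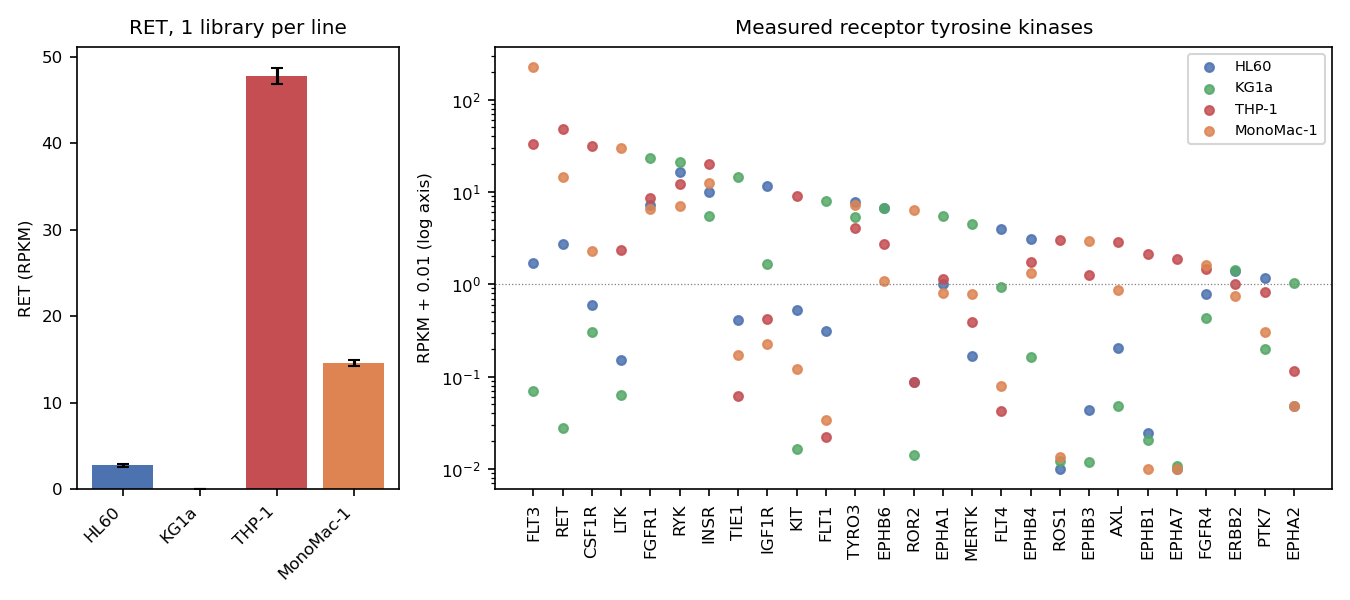
Left, RPKM of RET as bars from 0 with 95% Poisson intervals for counting error only; right, RPKM of the 27 measured receptor tyrosine kinases with 0.01 added on a log axis, 1 point per line and a dotted line at 1, with 1 library per line. RET lies at 47.8 RPKM in THP-1, 14.6 in MonoMac-1, 2.74 in HL60 and 0.0175 in KG1a.

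Among the 27 measured receptor tyrosine kinases, 2 were at least 4-fold higher in both MLL-AF9 lines than in the other lines, 0 were lower by that rule and 25 met neither. These were RET and FLT3, a growth factor receptor of blood progenitors, at 33.4 RPKM in THP-1 and 225 in MonoMac-1 against 1.69 in HL60 and 0.0597 in KG1a. The leading kinase was RYK in HL60 (16.3 RPKM) and FGFR1 in KG1a (23.5 RPKM). The numbers of kinases at 1 RPKM or more were 12 in HL60, 12 in KG1a, 19 in THP-1 and 13 in MonoMac-1. As a group the kinases were not called by camera (adjusted p = 0.611), and their median of 0.21 on the log2 scale turned to -0.13 under quantile normalization. For RET itself limma gave 3.82 ± 0.88 (log2, SE; adjusted p = 0.367), so the difference did not exceed the spread between lines at the threshold. In a limma fit adjusted over the list alone, RET passed in the RET list (1 of 2) and 0 of 27 passed among the kinases, and 0 of either passed over all genes.

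The comparison of THP-1 and MonoMac-1 with HL60 and KG1a asked which transcripts set the MLL-AF9 lines apart. Both MLL-AF9 lines are monocytic, and neither HL60 nor KG1a is. Differences tied to the fusion, to the lineage or to single lines therefore cannot be told apart, for RET as for all other genes. Of the 12 genes with the largest gaps on the higher side, 4 belonged to the monocyte list (IRF8, LYZ, LILRB4 and CD68) and 1 to the HLA class II list (HLA-DRB1). IRF8, a transcription factor of the monocyte lineage (chromosome 16, 85932774 to 85956211), stood at 231 RPKM in THP-1 and 163 in MonoMac-1 against 0.599 in HL60 and 0.0216 in KG1a. LYZ, which encodes lysozyme, stood at 510 and 4837 against 11.99 and 1.13 RPKM. CD68, a lysosomal protein of macrophages, stood at 170 and 219 against 4.34 and 0.596. On the lower side were CD69, an early activation antigen of lymphocytes, at 0.0634 RPKM in THP-1 and 0.159 in MonoMac-1 against 62.2 in HL60 and 55.2 in KG1a, and CCND2, a G1 cyclin, at 0.170 and 0.180 against 30.3 and 46.0.

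By the 4-fold rule 181 genes were higher in both MLL-AF9 lines and 43 were lower. By any margin 22.1% of all measured genes were higher in both MLL-AF9 lines than in both other lines and 19.6% lower, where 16.7% per direction is due if the 4 lines are exchangeable; the lists are set beside the shares of all genes. The split that paired HL60 with THP-1 gave 9 and 19 genes, and the split that paired HL60 with MonoMac-1 gave 19 and 19. Among the other leading genes of the higher side were BARX1, a homeobox gene (86.4 RPKM in THP-1 and 117 in MonoMac-1 against 0.290 in HL60, and listed at 0 in KG1a), FCGRT, the neonatal Fc receptor (83.6 and 87.4 against 0.333 and 0.293), and AGT, which encodes angiotensinogen (116 and 62.1 against 0.0508 in KG1a, and listed at 0 in HL60). LILRB4, an inhibitory receptor of monocytic cells, reached 57.0 RPKM in THP-1 and 35.3 in MonoMac-1, the metallothionein gene MT1E 48.2 and 53.9, and C20orf103 (LAMP5) 53.6 and 102, and all 3 were listed at 0 in HL60 and KG1a. The other leading genes were LPHN2 (56.2 and 44.3 RPKM), NAPSB (36.9 and 38.6) and HLA-DRB1 (57.4 and 120), each under 1 RPKM in HL60 and KG1a. The leading genes of the lower side included the lymphocyte genes PTPRCAP (91.5 RPKM in HL60 and 303 in KG1a against 0.412 in THP-1 and 1.03 in MonoMac-1) and IL2RG, the common gamma chain of cytokine receptors (126 and 175 against 1.67 and 7.42). ITM2A (60.8 and 270 against 1.26 and 0.228), ZBTB16, a transcriptional repressor (12.4 and 12.7 against 0.0593 and 0.0648), and HMGA2, a chromatin protein (33.3 and 10.8 against 0.0062 and 0.0028), were also among them. So were PLCH1 (11.6 and 22.6 against 0.0418 and 0.00965), ABLIM1, GALNT14 and JUP, the last 3 with gaps of 3.18, 3.08 and 2.85 on the log2 scale, and CD34, at 494 RPKM in KG1a and 12.9 in HL60. The HL60 value of CD34 was 2.62% of that in KG1a, a share at which many genes abundant in KG1a lay in HL60.

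**Figure D2:**
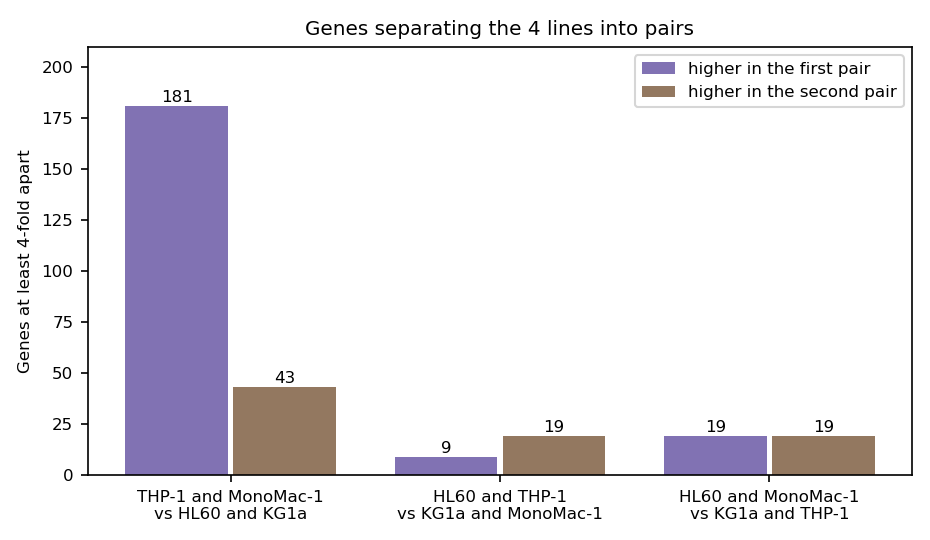
Number of genes at least 4-fold apart between pairs of lines, for the 3 ways to split the 4 lines, as bars from 0. The split of THP-1 and MonoMac-1 from HL60 and KG1a gives 181 and 43 genes, and the other splits give at most 19 in either direction.

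With limma, 0 genes passed after adjustment over all 12976 genes, and the lowest adjusted p was 0.0724, for genes that included IRF8 (log2 difference 7.26, SE 0.43) and CD69 (-5.75, SE 0.39). At an unadjusted p under 0.05 there were 767 higher and 342 lower genes where 649 in total were due by chance, and with only genes of at least 5 RPKM in some line 10 higher and 1 lower gene passed. The counts by the 4-fold rule held for these 4 lines: without HL60 they were 560 and 486, without KG1a 317 and 116, without THP-1 415 and 98, and without MonoMac-1 415 and 104.

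The monocyte and macrophage markers had the lowest camera p of the 19 tested lists. Of 31 measured members 10 were at least 4-fold higher in both MLL-AF9 lines, 0 lower and 21 neither. Besides IRF8, LYZ, CD68 and LILRB4 these were CCR2, a chemokine receptor of monocytes (68.3 RPKM in THP-1 and 37.2 in MonoMac-1 against 0.0725 in HL60 and 0.861 in KG1a), TLR2 (33.7 and 37.2 against 2.93, and listed at 0 in KG1a), S100A8, S100A9, CD36 and MPEG1. Without regard to size, 22 members were higher in both MLL-AF9 lines than in both other lines and 0 were lower (22.1% and 19.6% of all genes). The median difference was 2.26 on the log2 scale, and camera called the list (adjusted p = 5.26e-13; adjusted p = 0.706 with an estimated correlation). With limma 11 members passed when adjusted over the list alone and 0 over all genes. CD14, the endotoxin co-receptor, was low in all 4 lines, at 4.14 RPKM in MonoMac-1, 1.28 in THP-1 and under 0.1 in HL60 and KG1a.

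HLA class II genes were also higher in the MLL-AF9 lines. Of 15 measured members 3 were at least 4-fold higher, 0 lower and 12 neither, and 9 were higher in both lines than in both other lines by any margin (22.1% of all genes) while 0 were lower. The 3 genes were HLA-DRB1, HLA-DRB5 (13.7 RPKM in THP-1 and 19.95 in MonoMac-1 against 0.172 and 0.0982) and HLA-DQB1 (11.7 and 6.65 against 0.166 and 0.0468), of which the DRB genes are near-identical copies. The median difference was 2.28 on the log2 scale (camera adjusted p = 9.28e-06; adjusted p = 0.706 with an estimated correlation), and limma called 3 members adjusted over the list alone and 0 over all genes.

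Target genes of MLL fusions outside the HOXA cluster were higher as a group. Of 19 measured members 2 were at least 4-fold higher, FLT3 and C20orf103, 0 were lower and 17 met neither, and 10 were higher in both MLL-AF9 lines by any margin (22.1% of all genes) while 0 were lower. PBX3, a cofactor of HOX proteins, stood at 57.5 RPKM in THP-1 and 51.4 in MonoMac-1 against 2.96 in HL60 and 18.6 in KG1a. CDKN2C, a cell cycle inhibitor, stood at 121 and 135 against 22.3 and 54.05. MEIS1, a HOX cofactor, was measured at 18.6 RPKM in MonoMac-1 but at 0.0226 in THP-1, and MEF2C at 21.9 in THP-1 but at 0.208 in MonoMac-1. The median difference was 0.96 on the log2 scale (camera adjusted p = 0.000117; adjusted p = 0.706 with an estimated correlation), with 3 members passing limma adjusted over the list alone and 0 over all genes.

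The HOXA cluster did not separate the pairs. Of 11 measured members 0 were 4-fold higher or lower, and camera gave an adjusted p of 0.987 and a median difference of 0.14 that became -0.04 under quantile normalization. HOXA9 stood at 28.6 RPKM in THP-1 and 59.7 in MonoMac-1, but at 93.4 in KG1a and 2.65 in HL60, a value near the share at which KG1a genes lay there. Of the HOXB cluster 2 of 10 members were measured, too few for a test: HOXB2 at 38.3 RPKM in KG1a and 1.02 in HL60, which is 2.66% of KG1a and 0 after removal of that share, and HOXB4 at 1.79 in THP-1. Of 18 genes of MLL and its fusion-partner complex 0 were 4-fold apart, with a median of -0.39 (camera adjusted p = 0.0853). By any margin 1 was higher and 8 were lower in both MLL-AF9 lines (22.1% and 19.6% of all genes). After 2.71% of the KG1a values was taken off HL60, a step chosen after the data were seen, 7 were lower. The median level of the list was 26.8 RPKM in KG1a, 17.8 in HL60, 15.6 in THP-1 and 16.3 in MonoMac-1. MLL (KMT2A) itself stood at 7.10 RPKM in THP-1 and 5.31 in MonoMac-1 against 9.0 in HL60 and 36.6 in KG1a, values that do not separate normal from fusion transcripts.

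**Figure D3:**
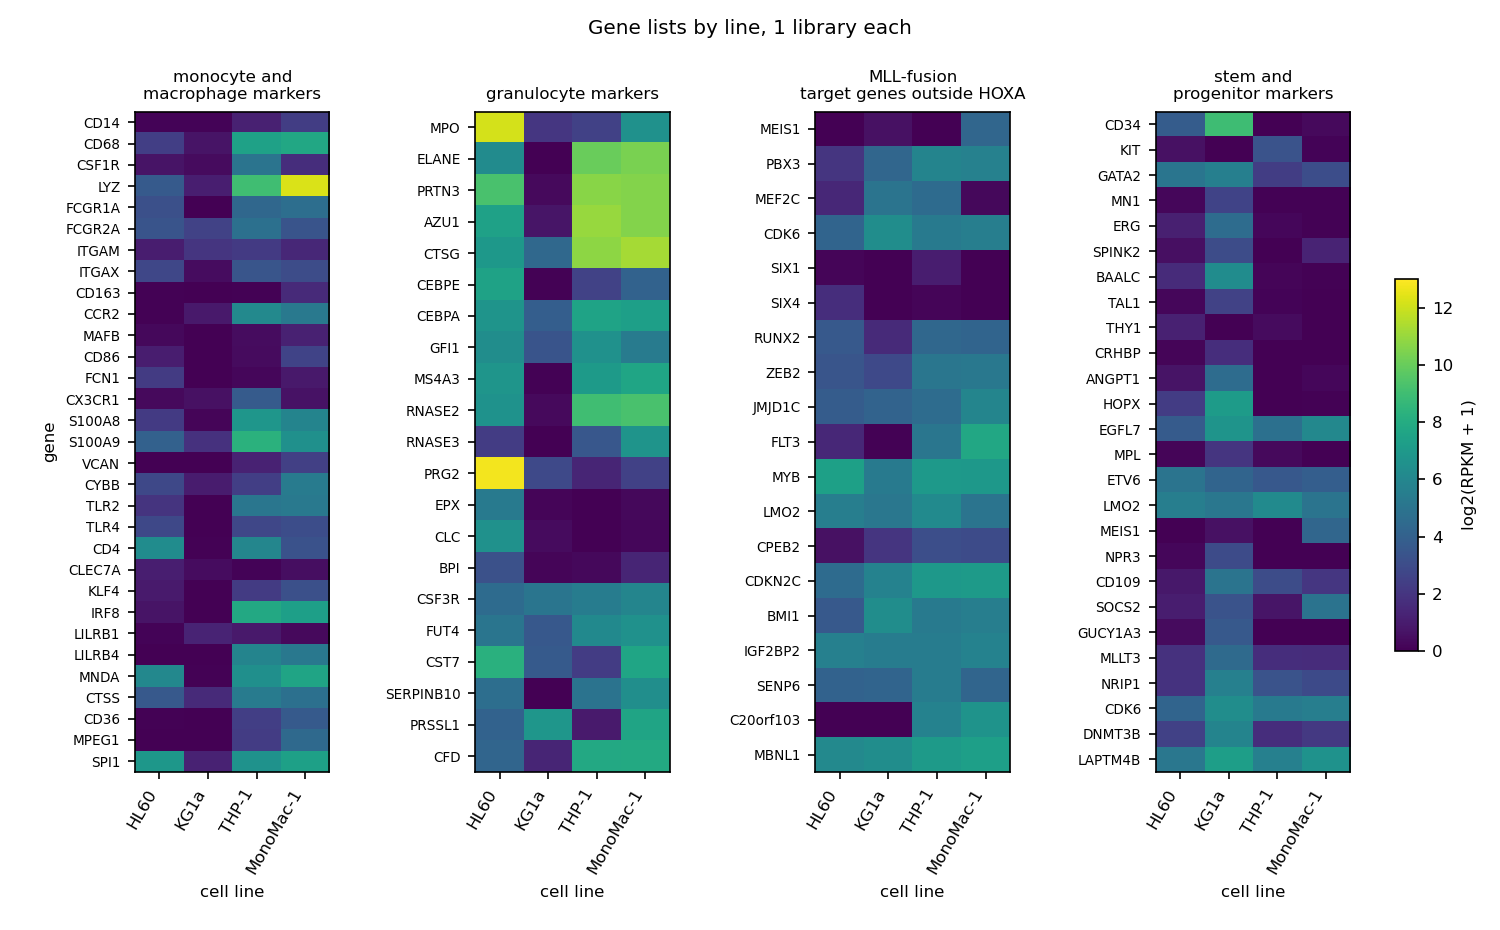
Expression of the measured members of 4 gene lists fixed beforehand, as log2(RPKM + 1) in color, with genes down the side and the 4 lines across, 1 library each. Of the monocyte markers 22 of 31 are higher in both THP-1 and MonoMac-1 than in both other lines, and of the stem and progenitor markers 14 of 26 are lower (6 after removal of the KG1a share from HL60).

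Granulocyte markers were higher in the MLL-AF9 lines by camera, but HL60 was not low in them: the median level of the list was 93.2 RPKM in HL60, 43.8 in THP-1, 104 in MonoMac-1 and 0.678 in KG1a. Of 21 measured members 5 were at least 4-fold higher, 0 lower and 16 neither, with 12 higher and 2 lower (PRG2 and CLC) by any margin (22.1% and 19.6% of all genes). The 5 were ELANE, CTSG, AZU1, RNASE2 and CFD. ELANE, a protease of azurophil granules, stood at 1042 RPKM in THP-1 and 1313 in MonoMac-1 against 76.6 in HL60 and 0.0355 in KG1a, AZU1 at 2033 and 1536 against 175 and 0.678, and CFD, which encodes complement factor D, at 227 and 238 against 17.96 and 1.55. The median difference was 2.05 (camera adjusted p = 0.0118; adjusted p = 0.706 with an estimated correlation), and limma called 2 members adjusted over the list alone and 0 over all genes. The call was lost without KG1a (adjusted p = 0.608) and without MonoMac-1 (adjusted p = 0.210).

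Stem and progenitor markers were highest in KG1a, and were called lower in the MLL-AF9 lines by camera, a call that rested on KG1a. Of 26 measured members 2 were at least 4-fold lower (CD34 and HOPX), 0 higher and 24 neither, with 14 lower and 0 higher by any margin (19.6% and 22.1% of all genes). After the KG1a share of 2.71% was taken off the HL60 values, 6 of the 26 remained lower in both MLL-AF9 lines (17.7% of all genes were lower after this step) and 0 met the 4-fold rule. Of these, GATA2, ETV6 and ERG were left at 32.2, 31.6 and 0.588 RPKM in HL60. HOPX, CRHBP and GUCY1A3 were left near the floor, at 0.0732, 0.0763 and 0.0196. GATA2, a transcription factor of progenitors, stood at 4.20 RPKM in THP-1 and 7.45 in MonoMac-1 against 32.6 in HL60 and 48.2 in KG1a, and kept its direction after that step. BAALC stood at 0.136 and 0.0635 against 2.03 and 78.7, but its HL60 value was 2.58% of that in KG1a, and after the step it was not lower than in HL60. The median difference was -1.02 (camera adjusted p = 0.000267; adjusted p = 0.706 with an estimated correlation), and 0 members passed limma adjusted over the list alone or over all genes. The call was lost without KG1a (adjusted p = 0.242), and held after removal of the share (adjusted p = 0.00410).

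Histone genes of the core histone list were called higher by camera (14 measured, 0 at least 4-fold apart, 2 higher and 0 lower by any margin where 22.1% and 19.6% of all genes were, median 1.28, adjusted p = 0.0225; adjusted p = 0.706 with an estimated correlation). This rested on MonoMac-1, where HIST1H2BK stood at 332 RPKM and HIST1H2AC at 61.6 against 10.5 and 0.907 in THP-1; the list also held the linker histone gene HIST1H1C, at 183 against 4.09. Without MonoMac-1 the direction reversed (adjusted p = 0.334), and the call was lost without HL60 (0.159) and without KG1a (0.226). Limma called 0 members adjusted over the list alone and 0 over all genes.

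Further lists were not called. Of 12 measured T and NK cell markers 1 was at least 4-fold lower in the MLL-AF9 lines (IL32), 0 higher and 11 neither, with a median of -1.79. Camera gave an adjusted p of 0.0853, and of 0.200 after removal of the KG1a share from HL60. The median level of the list was 12.3 RPKM in KG1a, 0.884 in HL60, 0.190 in THP-1 and 0.373 in MonoMac-1. IL32 stood at 102 RPKM in KG1a and 4.70 in HL60 and no longer met the rule after the removal of the KG1a share, which left 5 of the 7 members that were lower by any margin, while 2 were higher before and after it (17.7% of all genes were lower and 21.9% higher after it). Of 21 surface antigens studied as drug targets 4 were at least 4-fold higher, 0 lower and 17 neither (adjusted p = 0.0855, 2 by limma adjusted over the list alone and 0 over all genes): LILRB4, CD70 (56.5 RPKM in THP-1 and 43.3 in MonoMac-1 against 8.57 in HL60 and 0.0179 in KG1a), CD276 and CCR1. The 25 proliferation genes held 0 genes 4-fold apart and had a median of -0.20 (adjusted p = 0.0853). Of 24 interferon-stimulated genes 1 was 4-fold higher (MX2) and 1 lower (IFITM1), with an adjusted p of 0.600. Of 21 inflammatory and chemokine genes 1 was 4-fold higher, the inflammasome gene NLRP3 at 37.6 RPKM in THP-1 and 21.7 in MonoMac-1 against 4.41 and 3.28 (list adjusted p = 0.276, 1 by limma adjusted over the list alone and 0 over all genes). The 14 genes of the BCL2 family held 0 genes 4-fold apart (adjusted p = 0.245), with BCL2 at 30.7 RPKM in THP-1 and 28.6 in MonoMac-1 against 6.70 and 11.1.

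Of 12 erythroid and megakaryocyte markers 1 was 4-fold lower, ITGA2B at 90.3 RPKM in KG1a and 7.26 in HL60 against 0.323 and 0.330 (adjusted p = 0.505), of 5 B cell markers 0 were 4-fold apart (adjusted p = 0.764), and of 5 stromal and epithelial markers 1 was 4-fold higher, the adhesion receptor PECAM1 at 17.7 and 34.2 RPKM against 3.26 and 0.0069 (adjusted p = 0.675; 1 by limma adjusted over the list alone and 0 over all genes). The erythroid and B cell lists had medians of 0.15 and 0.08 but means of -0.52 and -0.57 and a downward camera test. Under quantile normalization these medians turned to -0.02 and -0.27, and that of the stromal and epithelial list went from 0.16 to -0.03. The 14 reference genes held 0 genes 4-fold apart, with a median of 0.02, a mean of -0.09 and a downward test (adjusted p = 0.611). In the other not-called lists, limma adjusted over the list alone called 0 genes, as it did over all genes.

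THP-1 and MonoMac-1, both with MLL-AF9, were next compared with each other, as 1 library against 1 and without a test. THP-1 held more CHI3L1, a secreted glycoprotein of macrophages (1035 against 16.6 RPKM), more GAS6, a ligand of the TAM receptors (76.1 against 0.353), more TGFBI, an extracellular matrix protein (96.8 against 1.33), and more of the linker histone gene H1F0 (119 against 0.443). MonoMac-1 held more HLA-DRA (430 against 4.39 RPKM), FABP4, a fatty acid binding protein (92.97 against 0.172), SFRP2, a secreted WNT modulator (132 against 0.0434), and KCNE1L (306 against 0.117). CDKN2A, which encodes cell cycle inhibitors, stood at 149 RPKM in MonoMac-1 and was listed at 0 in THP-1. EMD, which encodes a nuclear membrane protein, stood at 44.4 RPKM in MonoMac-1 and at 0.0215 in THP-1.

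In all, 263 genes were at least 4-fold higher in THP-1 and 294 in MonoMac-1, together 4.29% of the measured genes. The other leading genes were BHLHE22, DEM1, C13orf18, PPIC, OTX1 and GSTM1 in THP-1, with differences of 5.14 (GSTM1) to 6.04 (BHLHE22) on the log2 scale, and PRSSL1, KLHDC7B, TPSD1 and PLA2G16 in MonoMac-1 (-5.39 for PLA2G16 to -6.62 for PRSSL1). HLA class II genes were lower in THP-1, with a median difference of -1.53 (percentile 0 among random lists), and 7 of 15 members at least 4-fold lower and 0 higher, among them CIITA, the class II transactivator (0.250 against 5.85 RPKM). HOXA genes had a median of -1.04 (percentile 0), with 4 of 11 at least 4-fold lower in THP-1, such as HOXA7 (1.12 against 23.2 RPKM), and 2 higher, HOXA11 (12.2 against 0.393) and HOXA13 (10.6 against 0.0149). Core histone genes had a median of -2.85 (percentile 0), with 10 of 14 lower by 4-fold. B cell markers had a median of -0.97 (percentile 1.53), with 2 of 5 lower by 4-fold and 0 higher, and stromal and epithelial markers one of -0.88 (percentile 2.15), with 1 of 5 lower and 0 higher. Granulocyte markers had a median of -0.43 (percentile 1.26), with 4 of 21 lower and 0 higher, and monocyte markers one of -0.34 (percentile 0.94), with members on both sides, 3 of 31 higher and 4 lower.

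HL60 and KG1a, the lines without the fusion, differed more widely, again as single libraries without a test. Of the 10 leading genes of HL60, 6 belonged to the granulocyte list. MPO, which encodes myeloperoxidase, stood at 4610 RPKM against 3.10 in KG1a, PRG2, the eosinophil major basic protein, at 7020 against 6.38, and PRTN3, a granule protease, at 615 against 0.237. CEBPE, a transcription factor of granulocyte maturation, stood at 178 against 0.0409 and MS4A3 at 110 against 0.0443. KG1a showed the progenitor antigen CD34 (494 against 12.9 RPKM), the protease gene CTSW of cytotoxic lymphocytes (271 against 7.78) and HOPX (142 against 3.92). The cytoskeletal linker MSN (424 against 11.6) was low in HL60 alone, with 334 RPKM in THP-1 and 297 in MonoMac-1.

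There were 532 genes at least 4-fold higher in HL60 and 805 in KG1a, together 10.3% of the measured genes. The other leading genes of HL60 were DYSFIP1 (530 against 0.112 RPKM), BEX1 (511 against 0.124), AZU1, GTSF1 and IMPA2, and those of KG1a were PCDH10, C19orf77, KIAA0125, ESAM, STAB1 and RHAG. All 10 leading genes of KG1a lay in HL60 at 2.49% to 2.87% of their KG1a level, and 369 of the 805 genes lay within 1.5 times of 2.71%. Granulocyte markers had a median difference of 4.66 (percentile 100), with 18 of 21 at least 4-fold higher in HL60 and 1 lower, PRSSL1. Monocyte markers had a median of 0.94 (percentile 100), with 11 of 31 higher and 0 lower, such as CD4 (79.8 against 0.0451 RPKM) and SPI1, the myeloid transcription factor PU.1 (117 against 1.41). B cell markers had a median of 2.31 (percentile 99.97), with 3 of 5 higher, IGLL1, CD79A and CD79B, and 0 lower, and stromal and epithelial markers one of 1.20 (percentile 99.7), with 2 of 5 higher and 0 lower. HLA class II and inflammatory genes had medians of 0.46 and 0.34 (percentiles 98.3 and 98.75), with 1 of 15 and 6 of 21 higher and 0 and 4 lower.

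Several lists were higher in KG1a, with HL60 values near that share for members such as ANGPT1, CD247 and RSAD2. Stem and progenitor markers had a median of -2.41 (percentile 0), with 18 of 26 at least 4-fold lower in HL60, such as ANGPT1 (0.591 against 23.1 RPKM) and ERG (1.19 against 22.8). T and NK cell markers had a median of -2.38 (percentile 0), with 8 of 12 lower, such as CD247 (1.46 against 56.1) and CD7 (0.562 against 21.5). Interferon-stimulated genes had a median of -1.74 (percentile 0), with 10 of 24 lower, such as RSAD2 (1.69 against 75.3) and OAS3 (0.764 against 25.1). HOXA genes had a median of -1.61 (percentile 0.04), with 5 of 11 lower and 1 higher, HOXA13 (3.85 against 0.0065). The MLL complex had a median of -0.70 (percentile 0.16).

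**Figure D4:**
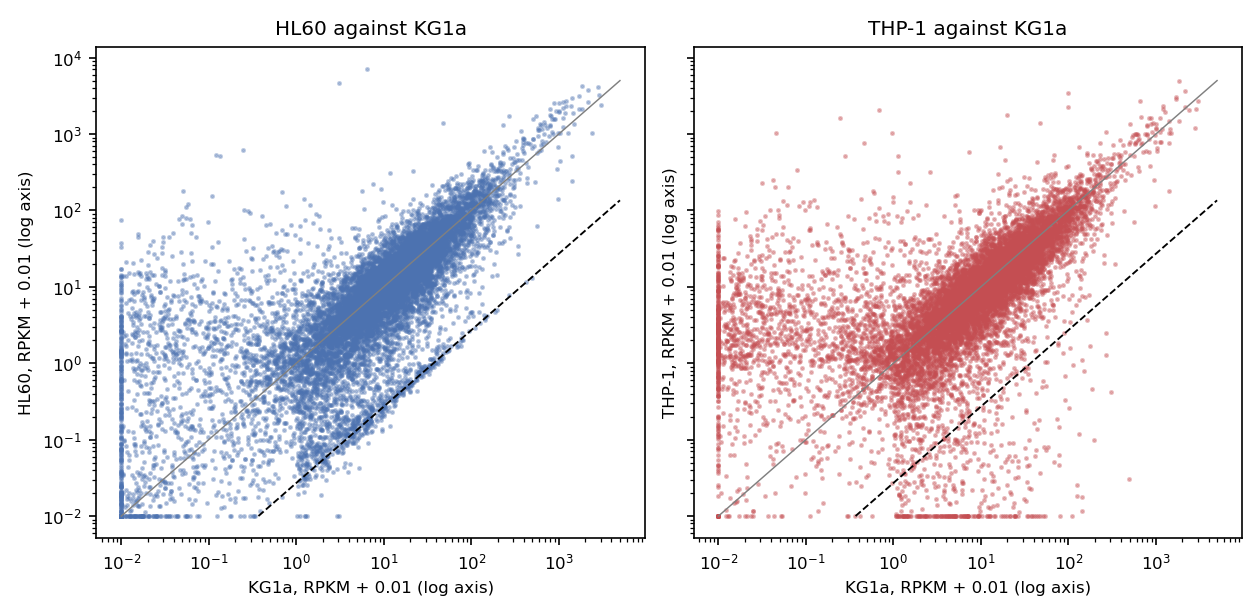
RPKM of each gene in HL60 (left) and THP-1 (right) against KG1a, with 0.01 added and log axes, 1 point per gene; the solid line marks equal levels and the dashed line 2.71% of the KG1a level. In HL60 nearly all genes abundant in KG1a lie on or above the dashed line, with 1 of 3670 genes at 20 RPKM or more in KG1a under 2% of it, and in THP-1 91 lie under 2%.

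The line-restricted genes gave each line its own set. Of the HL60 genes 5 belonged to the granulocyte list: MPO, CEBPE, PRG2, CLC, the Charcot-Leyden crystal protein, at 93.2 RPKM, and EPX, eosinophil peroxidase, at 38.5, the last 2 under 1 RPKM in the other 3 lines. IGF2BP1, an RNA-binding protein, reached 35.5 RPKM in HL60 and MZB1 48.4. THP-1 was set apart by CHI3L1, BHLHE22 (64.9 RPKM), C13orf18 (56.0), PPIC (64.9), TGFBI and TIMP3, an inhibitor of metalloproteinases (29.4). MonoMac-1 was set apart by KCNE1L, SFRP2, FABP4, HLA-DRA, PLA2G16 (40.9 RPKM) and HP, which encodes haptoglobin (62.2). By the 8-fold rule 22 genes were restricted to HL60, 142 to KG1a, led by CD34, PCDH10 (198.3 RPKM), KIAA0125 (143), ESAM (151), STAB1 (125) and HOPX, 60 to THP-1 and 54 to MonoMac-1. For 121 of the 142 KG1a genes, HL60 lay within 1.5 times of 2.71% of the KG1a level. Lower than in all other lines by the same rule were 14 genes in HL60, 108 in KG1a, 8 in THP-1 and 4 in MonoMac-1. Without THP-1 the count of MonoMac-1 was 166 and that of HL60 40, without MonoMac-1 the count of THP-1 was 183, and without KG1a the count of HL60 was 40. Among the copy-number landmarks of HL-60, a list too small to be tested, MYC stood at 596 RPKM in HL60 and at 113 (THP-1) to 141 (KG1a) elsewhere. CDKN2A stood at 3.28 RPKM in HL60 and CDKN2B at 0.419, and both were listed at 0 in THP-1.

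The transcriptomes of THP-1 and MonoMac-1 were the closest of the 6 pairs of lines. Pearson's r across 12976 genes was 0.890 (Spearman's rho 0.887) for this pair, 0.854 (0.847) for HL60 and MonoMac-1, and 0.842 (0.830) for HL60 and THP-1. HL60 and KG1a gave 0.803 (0.796), KG1a and THP-1 0.727 (0.728), and KG1a and MonoMac-1 0.726 (0.731). KG1a was thus in each of the 3 least similar pairs. After removal of the KG1a share from HL60 the order by r was kept, with 0.780 for HL60 and KG1a, 0.840 for HL60 and THP-1 and 0.852 for HL60 and MonoMac-1. These correlations are across genes, which are not independent replicates.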

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

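Removal of the KG1a share from HL60 was chosen after the results were seen; the other alternatives were fixed beforehand. No paired analysis was possible because each line has 1 library. Averaging repeated entries left all 295 single-gene or list values and 14 main results within tolerance (counts within 1.5 times, single genes within counting error, list calls on the same side), with 293 in place of 294 genes higher in MonoMac-1, and quantile normalization left 278 of the former and all 14 of the latter within it. No alternative matched the depth of the libraries; the value of RET in KG1a rested on 6.8 fragment equivalents. Where a count moved and its alternative's construction does not show why, the cause was not tested.

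By construction the pseudocount and the fold rule move counts of genes. At a pseudocount of 0.1, 435 genes were higher and 141 lower in the MLL-AF9 lines, 690 were higher in THP-1 and 601 in MonoMac-1, 1017 in HL60 and 1454 in KG1a, and 60 (HL60), 383 (KG1a), 200 (THP-1) and 129 (MonoMac-1) were line-restricted. At a pseudocount of 5 these were 59 and 7, 72 and 107, 164 and 243, and 9, 32, 14 and 19. With a 2-fold rule there were 568 and 205, 993 and 1256, and 1694 and 2319 genes, and a 4-fold rule for line-restricted genes gave 59 (HL60), 366 (KG1a), 147 (THP-1) and 137 (MonoMac-1). The correlation of THP-1 with MonoMac-1 was 0.850 and 0.908 at pseudocounts of 0.1 and 5, 0.940 without a filter and 0.849 with a filter at 5 RPKM. Under median-of-ratios scaling RET was 49.4 RPKM in THP-1 and 14.3 in MonoMac-1, outside their counting intervals.

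With limma 0 genes passed at any pseudocount, scaling or left-out line, and 10 higher and 1 lower with a filter at 5 RPKM, where fewer genes were tested. When a line was left out, the lone line of its pair was taken to vary like the other pair. Leaving out each line gave 317 to 560 higher and 98 to 486 lower genes in the MLL-AF9 lines, since fewer lines had to clear the rule (highest without HL60, lowest without KG1a for higher and without THP-1 for lower genes). Line-restricted genes ranged from 30 (without MonoMac-1) to 40 (without KG1a or THP-1) in HL60, 68 (without KG1a) to 183 (without MonoMac-1) in THP-1, and 70 (without KG1a) to 166 (without THP-1) in MonoMac-1.

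Camera called 6 lists as planned and 0 with an estimated correlation; leaving out a line gave 4 (without KG1a) to 8 (without HL60). The histone list reversed without MonoMac-1 (adjusted p from 3.27e-12 without THP-1 to 0.334 without MonoMac-1, and 0.706 with an estimated correlation), and quantile normalization took it to 0.0526. At a pseudocount of 0.1 the granulocyte (0.0501) and histone (0.0859) lists fell short, as both did without a filter (0.0637 each). The MLL complex and proliferation lists passed at a pseudocount of 5 (0.0489 and 0.0454), the proliferation list also without a filter (0.0460), and with a filter at 5 RPKM the T and NK (0.0112) and surface antigen (0.0144) lists passed. The cause was not tested. With the estimated correlation the 6 called lists shared an adjusted p of 0.706. Their unadjusted camera p ran from 0.0432 (MLL-fusion targets) to 0.483 (granulocyte markers). For the MLL-fusion targets the estimated correlation was -0.039, below the preset 0.01, so a higher correlation is not why that call was lost. For the other called lists it ran from 0.185 (monocyte markers) to 0.685 (histone genes). The run with an estimated correlation also rests on the 2 residual degrees of freedom, and the preset run does not. Its p-values therefore do not measure the correlation alone.

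After removal of the KG1a share from HL60, 180 of the 181 higher and 35 of the 43 lower genes remained. The 8 lost were ARHGAP22, C10orf128, CD34, DYSF, GFI1B, HOPX, IL32 and PCDH10, and the gap of CD34 turned to -0.33. Camera called 6 lists, and there were 540 genes higher in HL60 and 897 in KG1a.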

Other observations

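The tests of the KG1a share, of S phase and of the silent genes of THP-1 were chosen after the results were seen; those of RNAs without a poly(A) tail and of genes of 1 exon were set before theirs were.

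Metallothionein genes, whose products bind zinc and copper, were not all highest in the same line (MT1G, MT1X and MT2A were chosen after their values were seen). MT1G followed MT1E, at 12.4 RPKM in THP-1 and 61.9 in MonoMac-1 against 0.0438 in HL60, and was listed at 0 in KG1a. MT2A was highest in HL60, at 220 RPKM, with 7.54 in KG1a, 23.2 in THP-1 and 49.8 in MonoMac-1, and MT1X ranged from 4.40 in KG1a to 62.6 in MonoMac-1. These genes have close copies, and their values are uncertain.

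Of the 21 measured genes of the inflammatory list 2, the chemokine genes CCL2 and IL8, were restricted to HL60 by the 8-fold rule; against KG1a, 6 members were at least 4-fold higher in HL60 and 4 lower. CCL2 stood at 33.5 RPKM in HL60, 0.362 in THP-1 and 0.761 in MonoMac-1 and was listed at 0 in KG1a. IL8 stood at 85.1 RPKM in HL60 against 0.400 in KG1a, 1.89 in THP-1 and 5.32 in MonoMac-1, and TNF at 39.6 against 0.0128, 5.38 and 10.1. KG1a instead led for ICAM1, at 12.1 RPKM against 0.560 (THP-1) to 2.14 (MonoMac-1). HL60 also led for the early B cell gene IGLL1, at 105 RPKM against 5.85 in KG1a, 0.0596 in THP-1 and 3.51 in MonoMac-1.

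Genes high in KG1a lay in HL60 at a near-constant low share. Over the 65 genes at 20 RPKM or more in KG1a and under 1% of that in both MLL-AF9 lines, the median share was 2.71% (quartiles 2.56% and 3.34%), with 51 within 1.5 times of it. Reads passing among all 4 libraries are argued against by 91 genes (THP-1) and 98 (MonoMac-1) of 3670 that lay under 2% of KG1a, where HL60 had 1. Expression by HL60 cells themselves is argued against by an interquartile range of 0.38 on the log2 scale, where 9 of the other ordered pairs of lines, with 4 to 41 genes each, gave 2.17 to 6.73. Some of these ranges rest on ratios near 0, as for THP-1 genes in KG1a, with a median of 0. The pairs with larger shares were THP-1 genes in MonoMac-1 (40 genes, median 20.65%) and MonoMac-1 genes in THP-1 (41 genes, median 18.6%). Their ranges were 5.40 and 3.82. For KG1a against THP-1 or MonoMac-1 0 genes met the rule, which needs an HL60 level under 1%. A hypothesis left open is therefore that KG1a cells, RNA or reads make up a few percent of the HL60 library; the values do not separate these sources, and CD34, HOPX or T-lineage transcripts of HL60 may belong to KG1a.

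Genes of the core histone list were higher in MonoMac-1 than in the other 3 lines, by a median of 2.67 on the log2 scale (1.65 to 3.62), with 13 of 14 highest there; H1F0, a linker histone gene outside the list, was instead lowest there, at 0.443 RPKM against 5.09 (KG1a) to 119 (THP-1). The 95% bootstrap intervals here resample genes of 1 library per line as if independent (the estimated correlation of the histone list was 0.685), so they are too narrow and leave out variation between cultures. More cells in S phase is argued against by 9 DNA replication genes, whose median was -0.21 (-0.58 to 0.08). For less complete selection of polyadenylated RNA, 186 RNAs without a poly(A) tail had a median of -0.0065 (-0.10 to 0.06). Nearly all of these are small nuclear, nucleolar and similar RNAs, which a library may not hold as it holds longer transcripts. They therefore do not decide this cause, which is left open. For a processing difference that raises genes of 1 exon, 313 such genes had a median of 0.24 (0.13 to 0.37), with 114 of them highest in MonoMac-1. This lies above 0, but under the rise of 1 on the log2 scale set beforehand for this cause and under the 2.67 of the histone genes. It argues against such a difference as the whole cause if all genes of 1 exon are raised alike, and leaves a smaller part open. No exon annotation was used, and these genes were inferred from the values, as those whose length behind the RPKM matched their genomic span. A difference of the MonoMac-1 cells themselves, such as polyadenylated transcripts of the listed genes, is a hypothesis that no test here addressed, and whether the read processing, which looks different for this library, plays a part was not tested beyond genes of 1 exon.

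Neighbouring genes were silent in THP-1 and expressed in the other 3 lines. Neighbouring here means next in order on a chromosome among genes at 2 RPKM or more in the other 3 lines (8396 for THP-1). Genes below that level in between were passed over, so the pairs need not be adjacent in the genome. Of 13 genes under 0.1 RPKM in THP-1 and at 2 RPKM or more elsewhere, KLHL9, MTAP and CDKN2A on chromosome 9 and FUNDC1 and KDM6A on X (chosen after their values were seen) made 3 neighbouring pairs, where 10000 random placements gave 2 at most and 0.0203 on average. The lower depth of THP-1 is argued against by the 237 or more fragments that each would have given at the lowest level of the other lines. Loss of the DNA may explain MTAP, CDKN2A and FUNDC1, the 3 of the 5 genes with 0 bases in THP-1, but silencing would give the same and these cannot be told apart from RNA; KLHL9 had 100 bases, and KDM6A had 3200 (16 fragments, 1.63% of the lowest other level), which goes against loss of that whole gene unless they come from a similar gene. KG1a had 11 such pairs among 176 silent genes (3.52 on average at random, and as many in 8 of 10000 placements). MonoMac-1 had 1 among 22 (as many in 576 placements) and HL60 had 0 among 9. An excess of such pairs over random placement was therefore not particular to THP-1. With about 2.71% of the KG1a level in HL60, many genes expressed in KG1a could not fall under 0.1 RPKM there. The HL60 count therefore cannot be set beside the others.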
